A study of Laccaria bicolor
Populus tremula x Populus alba and Populus tremula x Populus alba with 5 samples.

How the data were processed

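RNA from poplar roots grown with or without an ectomycorrhizal fungus was sequenced as 5 paired-end libraries with reads of 150 bp. Per the labels, 3 libraries came from ectomycorrhizal (EcM) root tips of a hybrid poplar clone (Populus tremula x alba) after 14 days of contact with Laccaria bicolor S238N, and 2 libraries came from control roots handled alongside without the fungus. The labels call all 5 biological replicates. Per the labels' protocols, about 100 mg of tissue was ground per sample, the EcM harvest took all fungal and mixed material within 0.5 cm of a root, RNA was extracted on columns, and libraries were made with a stranded mRNA kit. The protocol names a 2% polyethylene glycol supplement to the extraction buffer for samples containing poplar roots and gives EcM as the example, so whether the control roots received it is not clear from the labels. All samples carry the same batch label.

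The authors deposited, for each library, a count of unique gene reads for each of 34699 genes, together with TPM and RPKM values. Per the file headers, the genes are the Populus trichocarpa version 4.1 models of Phytozome, 1 transcript identifier per gene; reads of the hybrid clone were therefore assigned to models of a related species. The aligner, the counting tool, the strand setting and any read filter are not given in the sources used here; DESeq2 is listed, without a version, in the submitters' processing notes. The deposited counts are whole reads and were analysed unchanged. The deposited TPM values have the same sum in every library and were used only for shares of the transcript pool and for an alternative test; the deposited RPKM values were used only to recover transcript lengths. Both are written with decimal commas.

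Identifiers are not paired with gene names or descriptions in the tables, and no annotation was used here. The 33 gene lists (nutrient transport, hormone, defence, cell wall, symbiosis and other groups) that had been fixed as patterns on gene descriptions could therefore not be tested, and genes are given by identifier only. The 3-digit prefix of an identifier stands for the chromosome in the Populus naming scheme, and T for unplaced scaffolds; locus numbers rise along the order of the deposited table for all 19 chromosome prefixes. No coordinates were used.

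The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) on the counts, with TMM scaling, edgeR's expression filter on the group and Benjamini-Hochberg adjustment over the 24114 genes kept; a gene was called at an adjusted p under 0.05. All 5 libraries entered, with group as the only term. TMM factors lay between 0.984 and 1.02. Standard errors of log2 fold changes are approximate, the fold change divided by the square root of its F. CPM values are unique reads scaled by library total and TMM factor, except in counts of genes detected at 1 CPM and of silent genes, where the library total alone was used. Counts were simulated for these 24114 genes with the real library sizes and means and a dispersion trend common to both groups. In them 50 genes each were changed by a fold of 1.5, 2, 4 or 16. The test recovered 84% of the 50 genes changed 2-fold and 46% of the 50 changed 1.5-fold, and 2.94% of its calls were false. Far more genes were called in the data, so these rates describe the simulated setting only. The rule for genes named in the text, with no names paired to identifiers, was the 2 largest rises and the 2 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups' libraries. It and the alternatives below were fixed before the data were examined, except where stated.

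Transcript lengths were recovered from the counts and RPKM. For a gene with unique reads only, RPKM is fixed by the count, the length and the library's read total, so the total was found that made lengths whole numbers within 0.05 bp. A length was accepted where at least 2 libraries gave the same whole number (24719 genes of the table, and 20199 or 83.8% of the genes tested). Simulated values for 8000 genes, made with the same formula, gave 100% right lengths among genes without shared reads. Lengths of genes with shared reads were not scored. The shortest accepted length among tested genes was 28 bp, below the read length of 150 bp. Genes whose length agreed in every library with reads were taken to have unique reads only (15897 of the genes tested). For correction of a length trend the remaining genes received the largest estimate over libraries, a lower bound. The unique reads were 2.15% to 2.37% fewer than the read totals behind RPKM. Neighbouring genes were compared in locus-number order over tested genes on chromosome prefixes, against 10000 shuffles of the calls within 20 bins of mean expression (one-sided), and runs against 2000 shuffles. Chromosome shares were compared with 10000 rotations of the calls along the ordered genes (two-sided). The length, neighbour, chromosome and silent-gene comparisons were chosen after the data were examined.

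Alternatives tried were 3 other scalings, DESeq2 1.42.0, limma-voom (limma 3.58.1), 2 other filters, thinning of every library to the smallest total, leaving out each library, a replicate block, stricter thresholds and, added after the data were examined, removal of the length trend by a lowess curve per library, limma on log2(TPM + 1), and genes with unique reads only. Samples were treated as unpaired, since the labels give the replicate numbers no shared origin. Libraries of one group were compared for duplication by chi-square over genes; the statistic per degree of freedom lay between 4.10 and 5.63, above sampling noise in all 4 pairs, so none was merged. Depth was 31722806 and 30558285 unique reads in the control libraries and 6685563, 8290510 and 6192443 in the EcM libraries, so 1 read stands for about 0.032 CPM in a control and 0.121 to 0.161 CPM in an EcM library. A group with no reads was given a floor of 3 reads over the group; floors cover counting error only.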

Results

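Poplar transcripts were compared between control roots and ectomycorrhizal (EcM) root tips, the organs in which the fungus Laccaria bicolor ensheathes a fine root and exchanges nutrients with it. The plant was a hybrid poplar clone (Populus tremula x alba) grown in vitro, and both groups were harvested at 14 days. The control group had 2 libraries, with 31722806 and 30558285 unique gene reads, and the EcM group had 3, with 6685563, 8290510 and 6192443. At least 1 read was found for 29303 and 29009 genes in the controls and for 27243, 27546 and 27386 genes in the EcM libraries. After every library was thinned to the smallest total the ranges overlapped, at 27350 and 27292 genes in the controls and 27161 to 27386 in the EcM libraries. At the level of 1 CPM, 23552 and 23556 genes were detected in the controls and 23429 to 23552 in EcM. No gene dominated a library, since the 10 most abundant genes held 2.28% ± 0.03 (SD, n = 2) of control reads and 2.72% ± 0.15 (SD, n = 3) of EcM reads.

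Libraries of a group resembled one another far more than libraries of different groups. Across genes, Spearman's rho of log2 CPM was 0.99 between the 2 controls, 0.98 for each of the 3 EcM pairs, and between 0.86 and 0.89 for the 6 pairs that crossed the groups. The first principal component held 83.7% of the variance. The coefficient of biological variation was 7.25% within the control group and 12.7% within the EcM group, and 10.2% over both.

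The comparison of EcM tips with control roots asked which poplar genes differ in abundance between them at 14 days. The fungus and the part harvested, root tips against roots, changed together, so no call can be credited to either alone. Of 24114 genes tested, 7185 were higher and 7160 were lower in EcM, together 59.5% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05, 3 EcM against 2 control libraries). Most of the called changes were small: 8275 genes, 57.7% of those called, changed by less than 2-fold. Among the called genes, 2872 were higher and 3198 lower by 2-fold or more, 837 higher and 934 lower by 4-fold or more, and 99 higher and 231 lower by 16-fold or more, where fitted folds of genes near 0 reads in a group depend on the prior count. The counts at 16-fold moved most with the method: 205 higher and 298 lower by DESeq2, 205 and 348 without an expression filter, 15 and 62 on log2(TPM + 1), which understates folds of low genes, and 60 and 168 over genes with unique reads only. The median log2 fold change was 0.84 for genes called higher and -0.92 for genes called lower. In 99.2% of the called genes every EcM library lay on the same side of both control libraries, against 73.0% of all tested genes and 20% expected by chance for 3 against 2 libraries. Of the called genes 50.1% were higher, a share that moved with the scaling. It was 45.7% with upper-quartile factors and 52.6% with no scaling beyond the library total. On the authors' TPM, whose test was added after the data were examined, 66.9% were higher, 9214 against 4568 lower. The median of all tested genes was then at 0.22 on the log2 scale. Restricted to genes with unique reads only, which tests 15924 genes, 4443 were higher and 4408 lower.

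**Figure D1:**
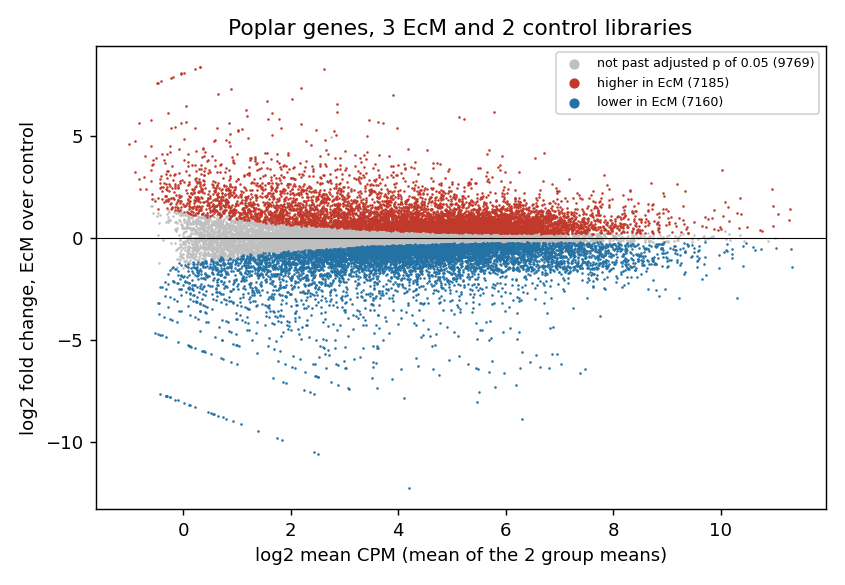
Log2 fold change (EcM over control) against log2 mean CPM, 1 point per tested gene; red, genes called higher in EcM (7185), blue, genes called lower (7160), grey, genes not past an adjusted p of 0.05. The lines of points at the lower left and upper left are genes at or near 0 reads in a group, whose fitted fold depends on the prior count.

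Called genes were found at every level of abundance and held most of the transcript pool in both groups. Genes called lower in EcM held 60.01% ± 0.37 (SD, n = 2) of the authors' TPM in control roots and 36.5% ± 1.3 (SD, n = 3) in EcM tips. Genes called higher held 16.6% ± 0.21 (SD, n = 2) in control roots and 35.7% ± 0.99 (SD, n = 3) in EcM tips. These sets were chosen by the same libraries, so the shares describe the size of the shift and do not test it. With tested genes in 5 equal bins of mean abundance, the most abundant bin began at 51.6 CPM, and in it 76.5% were called, with 2083 higher and 1609 lower and a median absolute log2 fold change of 0.70. In the least abundant bin, up to 4.73 CPM, 46.6% were called, with 1060 higher and 1188 lower and a median absolute log2 fold change of 1.68.

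The largest fitted falls were in genes without a read in any EcM library. Potri.003G204425.1, on chromosome 3, had 36.8 ± 5.3 CPM (SD, n = 2) in control roots and no read in any of the 3 EcM libraries, at least 262-fold lower against a floor of 3 reads over the EcM group (edgeR adjusted p = 1.45e-08). Potri.003G220200.1, also on chromosome 3, had 11.4 ± 2.3 CPM (SD, n = 2) in control roots and no read in EcM, at least 81.5-fold lower (edgeR adjusted p = 3.9e-07). The largest fitted rises were in genes without a read in either control. Potri.002G072800.2, on chromosome 2, had 2.49 ± 1.1 CPM (SD, n = 3) in EcM tips, at least 50.9-fold higher against the floor over the controls (edgeR adjusted p = 2.29e-05). Its length could not be recovered. In EcM replicates 1, 2 and 3 it had 1.35, 2.60 and 3.53 CPM of unique reads but 6.62, 8.30 and 8.17 TPM. With unique reads only, TPM would rise with CPM, so reads shared with other genes lie behind its TPM. Potri.003G143300.1, on chromosome 3, had 2.5 ± 2.0 CPM (SD, n = 3), with 4, 19 and 29 unique reads in the 3 EcM libraries, at least 51.0-fold higher (edgeR adjusted p = 0.00040), or at least 29.0-fold without EcM replicate 3. The bounds also follow the reads behind the floor: those of the rises were 25.0 and 25.1 without control replicate 1 and 25.9 and 25.96 without control replicate 2, and without EcM replicate 2 those of the falls were 158 and 49.2. Fungal reads assigned to poplar models would be found in EcM libraries only, so such an origin of the reads of both rises stays open, untested. The files do not pair these 4 identifiers with gene names.

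Silent genes were counted over the whole table. With no read in all 3 EcM libraries and at least 1 CPM in both controls there were 30 genes. With no read in both controls and at least 1 CPM in all 3 EcM libraries there were 6 genes, with CPM here scaled by the library total alone. Reads of the fungus assigned to poplar models could add to the genes silent in controls, which was not tested. The groups of libraries were not equally deep, with 62281091 reads behind a control zero and 21168516 behind an EcM zero. With every library thinned to the smallest total the counts were 26 and 24, but a zero in EcM then still rested on 3 libraries and a zero in controls on 2. With thinned libraries and 2 EcM libraries at a time, added after the data were examined, 67, 33 and 40 genes were silent in EcM and 35, 27 and 35 in controls. The 67 and the 35 beside it are without EcM replicate 3, the 33 and 27 without EcM replicate 2, and the 40 and 35 without EcM replicate 1.

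The direction of change followed transcript length. Among the 20199 tested genes with a recovered length, the shortest of 10 equal length groups (median 657 bp) had 58.4% of genes lower and 10.7% higher in EcM, with a median log2 fold change of -0.75. The longest group (median 4082 bp) had 8.76% lower and 65.4% higher, with a median of 0.56. The medians rose from each length group to the next, and Spearman's rho of fold change on length was 0.40 across genes, which are not independent replicates. The mean transcript length weighted by TPM was 1522 bp ± 12 (SD, n = 2) in control roots and 1796 bp ± 26 (SD, n = 3) in EcM tips. All 3 EcM libraries lay above both controls; an exact two-sided permutation test of 3 against 2 libraries cannot go below p = 0.1, so that test cannot reach 0.05 here whatever the difference. With the length trend removed, a choice made after the data were examined, 5651 genes were higher and 6795 lower; 4855 of the 7185 higher calls and 5563 of the 7160 lower calls were shared, and 147 genes called in both fits changed direction. All 4 genes named above kept their direction and an adjusted p under 0.05.

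**Figure D2:**
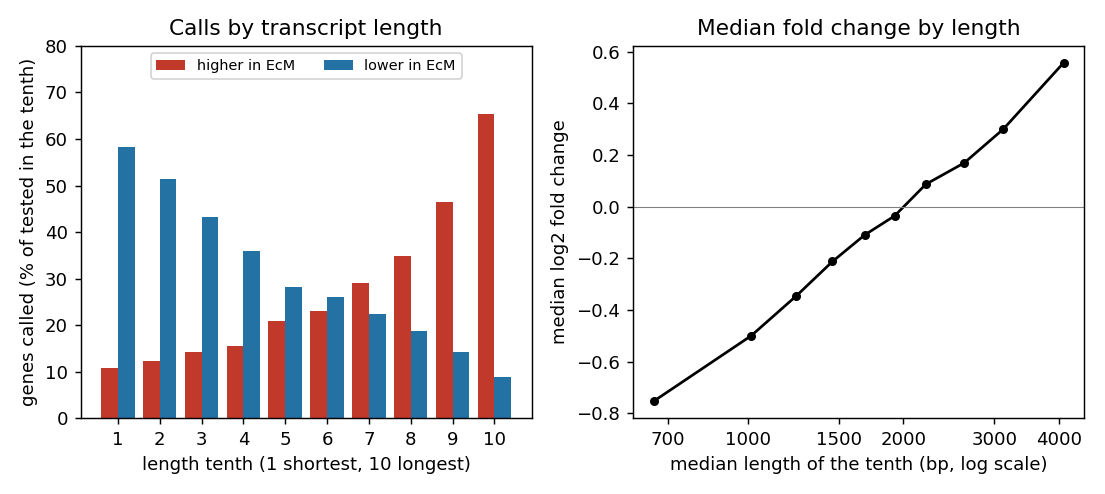
Left, percent of tested genes called higher (red) or lower (blue) in EcM in each of 10 equal groups of transcript length, from the shortest (1) to the longest (10). Right, median log2 fold change (EcM over control) against the median length of the same groups in bp on a log axis, rising from -0.75 to 0.56.

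Changed genes were spread over all 19 chromosomes. The share of tested genes called higher ranged from 26.9% on chromosome 8 to 34.8% on chromosome 11, and the share called lower from 26.4% on chromosome 17 to 32.2% on chromosome 16. None of the 38 shares passed an adjusted p of 0.05 against rotations of the calls along the genome (permutation test, two-sided, lowest adjusted p = 0.725). The lowest unadjusted permutation p was 0.022, for genes higher on chromosome 11, followed by 0.05 for chromosome 8. The 101 tested genes on unplaced scaffolds had 39.6% higher and 17.8% lower, against 29.8% and 29.7% on chromosomes, which was not tested.

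Neighbouring genes changed together more often than shuffled calls did. Of 23994 pairs of adjacent tested genes, both members were higher in EcM in 2502 pairs, against a mean of 2129 and a range of 2064 to 2193 in 95% of shuffles, a ratio of 1.18. Both were lower in 2444 pairs, against 2129, a ratio of 1.148 (one-sided permutation p = 0.0001 for each direction, the smallest that 10000 shuffles can give). At 3 genes apart the ratios were 1.07 and 1.04, and at 50 genes apart 1.02 and 1.01, within the shuffled range. Among genes with unique reads only, each was paired with the next such gene, so that pairs can span tested genes left out. The ratios for adjacent genes of that set were 1.09 higher and 1.09 lower (permutation p = 0.0001 for each). Both comparisons were chosen after the data were examined.

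Runs of adjacent tested genes called in the same direction were more frequent than in shuffled calls. There were 91 runs of 5 or more genes higher in EcM, against a mean of 39.8 and at most 63 in 2000 shuffles, and 83 runs lower, against a mean of 39.6 and at most 63 (permutation p = 0.0005 for each, the smallest these shuffles can give). The longest run of genes higher in EcM, 25 genes on chromosome 19 with locus numbers 14308 to 14374, had a median log2 fold change of 1.99, each gene between 0.76 and 3.64, and a median abundance that went from 2.92 CPM in control roots to 11.1 CPM in EcM tips. On chromosome 11 a run of 14 genes with locus numbers 35800 to 39200 had a median log2 fold change of 2.03, and a run of 10 with locus numbers 27501 to 29400 had a median of 2.52. These runs were singled out after their values were seen. None of the 25 genes on chromosome 19, 2 of the 14 and 3 of the 10 on chromosome 11 had unique reads only, so their counts are uncertain where near-identical copies share reads. With the length trend removed, 24 of the 25, 14 of the 14 and 10 of the 10 were still called higher. Only 5 of the 10 were in a run on chromosome 1 with locus numbers 211700 to 213900, whose median went from 0.66 to 0.30. In that run 6 of the 10 genes had unique reads only. Genes with no recovered length entered the removal with a lower bound, which takes out too little of the trend. The removal therefore favours keeping runs of such genes, and the contrast between the runs is not a fair test. Runs of 5 or more with the trend removed numbered 70 higher and 66 lower, which was not tested against shuffles. The longest run of genes lower in EcM was 9, against a mean of 7.99 in shuffles (permutation p = 0.25). The longest run higher was 12 genes without control replicate 1, 15 by DESeq2 or without an expression filter, 16 with the length trend removed and 7 over genes with unique reads only.

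**Figure D3:**
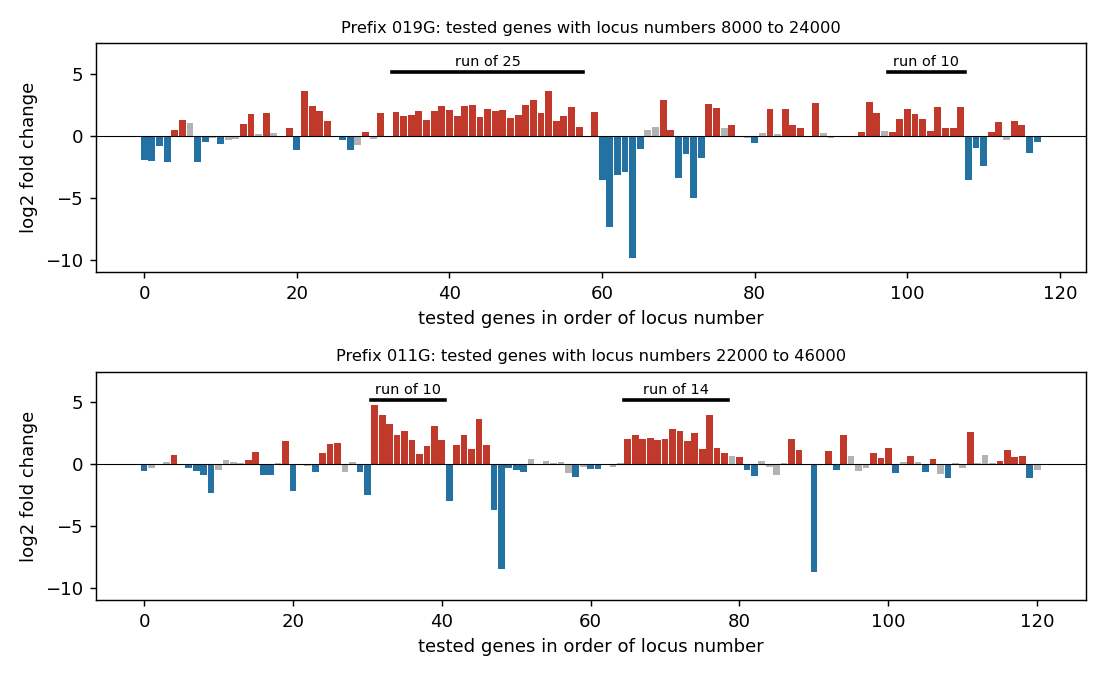
Log2 fold change (EcM over control) of tested genes in order of locus number on parts of chromosome 19 (top) and chromosome 11 (bottom), 1 bar per gene; red, called higher, blue, called lower, grey, not called. Black lines mark the runs of 25 and 10 genes higher in EcM on chromosome 19 and of 10 and 14 on chromosome 11.

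**Figure D4:**
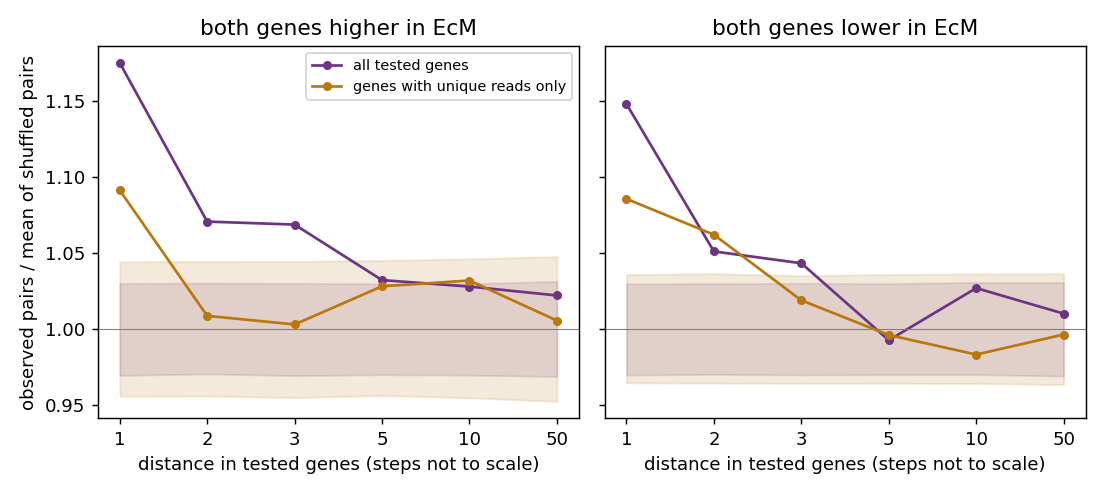
Observed pairs of genes that both rose (left) or both fell (right) over the mean of 10000 shuffles, against their distance in genes of the plotted set. Purple marks all tested genes and orange genes with unique reads only, whose pairs can span tested genes left out. Shaded bands hold 95% of shuffles, and the excess is largest for adjacent genes, at 1.18 and 1.148 over all tested genes.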

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

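Tests with the length trend removed, with TPM and with unique-read genes, and all results on length, neighbours, runs, 16-fold changes and silent genes, were added after the data were examined. The count of called genes (14345, with 7185 higher and 7160 lower) stayed within 1.5 times of its value under the 3 other scalings, DESeq2, limma-voom, both filters, thinning and an adjusted p under 0.01. Without 1 library, 10395 to 14386 genes were called, 5103 to 7121 higher and 5292 to 7265 lower; without a control the lone control is assumed to vary like the EcM libraries. Replicate numbers 1 and 2 occur in both groups without a stated shared origin. Across genes the deviations of same-numbered libraries from their group means correlated at -0.05 and 0.08. With the replicate block 13761 genes were called, 13190 of them shared with the fit without it. Replicate number 3 occurs in EcM only, so in the block fit that library adds nothing to the estimated difference between the groups. Under a threshold of 2-fold or more, 6070 genes remained past it, 2872 higher and 3198 lower, and glmTreat against 2-fold called 3249, with 1510 higher and 1739 lower; both ask for a larger change by construction. Genes with unique reads only gave 8851 calls, 4443 higher and 4408 lower, over 15924 genes tested. The authors' TPM gave 4568 lower and 9214 higher calls, 66.9% higher against 50.1% in the counts, with the median of all tested genes at 0.22 on the log2 scale; TPM is rescaled by the weighted mean transcript length, 1522 bp in controls and 1796 bp in EcM. No call shared with the main test changed sign under any alternative except 147 with the length trend removed and 1 with TPM. The 4 named genes kept their direction and an adjusted p under 0.05 wherever they were tested (edgeR, DESeq2 and limma, highest adjusted p = 0.0089). The 33 gene lists were not run, with every alternative planned for them, and rows are single transcripts per gene, so an unsummed fit was not needed. Depth limits EcM more than controls: a gene under about 0.14 CPM in EcM, or 0.049 CPM in controls, cannot be told from 0.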

Other observations

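The tests of length, neighbours and large falls in this part were chosen after the fold changes were first seen, although the bounds for each were set before its own result, except for the test of shared reads among genes with unique reads only and the tests of read-through with the length trend removed and among genes with unique reads only.

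Of the 8217 tested genes with evidence of reads shared with other genes, or with no recovered length, 37.4% were higher and 28.0% lower in EcM, against 25.9% higher and 30.6% lower of the 15897 genes with unique reads only. The median log2 ratio of EcM to control of the first set was 0.11 on unique reads and 0.10 on all reads behind RPKM. Its median length, 2015 bp, was also above the 1731 bp of the second set. The difference between the sets was not tested.

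The shift towards long transcripts in EcM is a pattern that touches many calls. A few abundant genes do not account for it, since the EcM excess in weighted mean length was 274 bp without the 100 most abundant genes and 263 bp with them, over genes with a recovered length. The lower depth of the EcM libraries does not either, as rho stayed at 0.41 after thinning. A recovery of RNA or fragments that depends on length and acts on every gene is a candidate explanation. The slope of log2 fold change on log2 length was positive in all 4 quartiles of expression, a ratio of 1.85 between the largest and the smallest. It rose from each quartile to the next, from 0.30 (bootstrap range 0.26 to 0.35) to 0.55 (0.52 to 0.58), so it was not equal at all levels of expression. Slopes between libraries of a group lay between -0.07 and 0.03. Any cause that follows the groups could give such slopes. RNA integrity, fragment size, any difference in the extraction buffer, fungal reads assigned to poplar models and the biology of the mycorrhizal tip all follow the groups here and stay open, untested, and the length of a transcript belongs beside any reading of its fold.

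Clusters of neighbouring genes that rose together may reflect gene families or domains that respond together, which could not be tested without gene names. Over all tested genes the ratio of adjacent pairs that both rose was 1.35 once the length trend was removed. This argues against the trend as the whole cause there. The removal used a lower bound for genes with no recovered length, which takes out too little of the trend. Among genes with unique reads only the ratio with the removal was 1.14. There 808 pairs both rose against at most 749 in 95% of shuffles, but the ratio was under the bound set for arguing against the trend. Without the removal, the ratio fell from 1.18 over all tested genes to 1.09 over genes with unique reads only. That step also leaves out families of like copies and genes with no recovered length, and its adjacent pairs can span genes left out. Over all tested genes the ratio was already 1.07 at 2 genes apart. The ratio of 1.09 met the bound of 1.1 or below set beforehand for shared reads as the cause. Because of these other differences, the fall still cannot tell whether reads shared between copies account for part of the excess. Among genes with unique reads only an excess remained, with 1159 pairs that both rose against at most 1109 in 95% of shuffles. Shared reads are left out of that set by its definition, so this shows only that some excess exists without them. Overlapping or read-through annotation is argued against as the whole cause only over all tested genes with the length trend removed. There the ratio 3 genes apart was 1.12 and outside the shuffled range. Its part in the adjacent excess of 1.35 stays open, since a ratio at greater distance cannot test it. As the whole cause it stays open over all tested genes without that removal. The ratio 3 genes apart was then 1.07, outside the range but under the bound of 1.1. It also stays open among genes with unique reads only, at 1.00 without and 1.04 with the removal, both within the range.

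Falls of 16-fold or more outnumbered rises of that size 2.33 to 1. The ratio was 2.03 with every library thinned to the smallest total, 2.26 or more under 3 other scalings and 1.99 with the length trend removed, so none of these accounts for the whole of it; it ranged from 1.45 by DESeq2 and 1.70 without an expression filter to 3.45 with a row mean of 10 or more and 4.13 on the authors' TPM. Genes without a read in a group and with at least 1 CPM in every library of the other numbered 30 in EcM and 6 in controls at full depth, and 33 to 67 against 27 to 35 with thinned libraries and 2 EcM libraries at a time. A loss of root cell types from the harvested tips, or repression in them, was not tested.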
